A study of Drosophila melanogaster with 2 samples.

How the data were processed

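Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open DNA and tags it for sequencing, in 2 libraries of ML-DmD17-c3 (D17), a Drosophila cell line derived from larval haltere imaginal disc. Both libraries belong to 1 group, and per the labels they were prepared with a commercial ATAC-seq kit. Nothing in the labels says whether they came from separate cultures. The submitters' processing notes name Trim Galore 0.6.4, Bowtie2 2.3.5.1, SAMtools 1.13, MACS2 2.2.6 and bedtools 2.29.2 and the builds BDGP6 and dm6, without saying what each was used for. Whether reads were shifted for the transposase offset, and whether the libraries were pooled before calling, is not given in the sources used here.

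The analysis started from 1 deposited peak list of 10 columns with no replicate named. Region names carry the letters HD, whose meaning is not given, and 442 of the numbers up to 27013 in those names are not in the list, for a reason not given. The list was taken as D17 because the series holds D17 libraries only, so each value is taken as the authors' value for the group, with no SD. The deposited fold enrichment is a ratio of the read pileup at the summit to the local background. The deposited columns of −log10 p-value and −log10 q-value belong to the summit, and the lowest −log10 q was 1.34, just past a q-value of 0.05. The deposited score equalled 10 times the −log10 q, rounded down, in 99.95% of regions. These meanings were taken from the column layout and the values. The score and fold were used only within this list, to describe, rank, filter and compare its regions and to recover the pileup.

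The summit pileup was recovered from fold and p-value, taking fold as (pileup + 1)/(background + 1) and p as a Poisson tail. A whole-number pileup met the deposited p-value within a relative error of 2.11e-05 in all 26571 regions. Intervals on fold are exact Poisson 95% intervals of the pileup at a fixed background. They cover counting error only, since fragments without molecular identifiers are not independent molecules, and the background's own error is left out.

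Gene positions came from a table of the Release 6 assembly, which has the coordinates of dm6. It gives the start and end of 17807 genes on the chromosomes used, 13946 of them protein-coding, without strand, transcripts or exons. The promoter planned before the data were examined therefore became a gene end: a window of 500 bp around either end of the annotated gene, which cannot separate a start from a stop. Exon and intron became gene interior. A planned motif test and a planned comparison with the 5′-most start site were not run, because sequence and strand were not used here.

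Summits at gene ends were compared with 1000 random placements of the regions within their chromosome (bedtools 2.31.1), and region counts per chromosome with 1000 placements across chromosomes. Both are permutation tests of position, two-sided, and the smallest p they can give is 0.000999. The span of a chromosome was its last coordinate in the peak list or gene table. Placements could fall anywhere in that span, including sequence where reads cannot be mapped. 26 gene lists written before the data were examined were tested by Fisher's exact test, two-sided, of members with a region overlapping an end window by at least 1 bp against all other protein-coding genes. Names that matched no single gene were left out of the lists: calypso, GMR, Dl, ban, Z4, nos and rye. They came from the Polycomb protein, eye, Notch, Hippo, insulator, germline and testis lists, in that order. Members without a protein-coding entry were left out too, among them oskar, whose name matched a non-coding RNA. Regions with a summit over 500 bp from every gene end were called distal and assigned to the protein-coding gene with the nearest end. A wide region can therefore overlap an end window and also count as distal, and it counts in both classes where genes are ranked by their number of regions. By permutation, the mean number per list was compared with 10000 random lists matched in 20 bins of territory, the bases nearest to a gene. Adjusted p-values are Benjamini-Hochberg over the 26 lists, with a threshold of 0.05. Scores of gene-end and distal regions were compared by a permutation test of medians with 100000 resamples. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.

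Named genes followed a rule fixed before the data were examined: every Hox gene, en and inv, up to 4 members of each other list with the most regions and up to 3 without a region at an end, the genes nearest to the 10 highest-scoring regions, and the 10 genes with the most distal regions. A gene named because it has a strong region at an end or among strong distal regions was chosen after its values were seen. Strong regions, the 10% with the highest fold, were also defined after the data were examined. The alternatives tried were other windows, merged regions, the 50% with the higher score, protein-coding ends, covered bases, other matching, isolated genes and lists without the member with the most distal regions.

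The list tests were tested on simulated data, with regions placed at random 20 times over the 13946 protein-coding genes. With regions planted at 50% of the lower ends of 3 lists and 3 distal regions per gene, the test of gene ends called the cuticle protein and chemoreceptor lists in all 20 runs and the Polycomb target list in 19. The distal test called the cuticle list in 20 runs, the chemoreceptor list in 11 and the Polycomb target list in 0, and still 0 with 8 planted regions per gene. A distal test that finds nothing therefore says little about lists whose members have long territories. With matched genes limited to the longest territory of the list, a version chosen after these results, all 3 lists were called in 20 runs. But this version also called unrelated lists: 11 of 360 tests with nothing planted, 23 of 360 with 3 planted regions per gene and 18 of 360 with 8. With nothing planted, 1 of 360 tests of gene ends and 0 of 360 distal tests on unrelated lists were called. Of 100 random placements treated as data, 8 had p under 0.05. The pileup was recovered exactly for 4963 of 4963 simulated summits made with the same formula.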

Results

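Chromatin accessibility was profiled in D17 cells, a line derived from larval haltere imaginal disc. There was 1 group of 2 libraries and 1 peak list, so the list was compared with random placement and genes with other genes, and there are no replicate values. Region names carry the letters HD, whose meaning is not given, and the list was taken as D17 because the series holds D17 libraries only. It held 26571 regions that covered 17.2 Mb, or 12.5% of the 137 Mb of chromosome spanned. The median width was 497 bp (197 to 9512 bp). The authors' fold enrichment over local background had a median of 1.90 and ran from 1.29 to 40.8. The recovered pileup at the summit had a median of 101 reads (62 to 2908), and the lowest local background, 44.4 reads, was shared by 39.7% of regions.

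The highest-scoring region lay inside Pkcdelta, a protein kinase C gene, at X 12437682 to 12438161, with a fold of 40.8 (95% Poisson interval 39.0 to 42.6). Next came regions inside CARPB (X 9809142 to 9810424, fold 26.0) and CG32700 (X 9515515 to 9515925, fold 30.3). A region inside the transcription factor gene Sox100B followed (3R 31074334 to 31075285, fold 28.5). The others of the 10 highest-scoring regions were inside alpha-Man-Ia or nearest to Ppr-Y (218791 bp away), Myo81F (443844 bp), inc (2876 bp), CR40190 (20705 bp) and CG1986 (3299 bp). Of the 30 highest folds, 13 were on X and 9 lay within 1 Mb of it, from 9.4 to 10.4 Mb. The cut at 30 and the window were chosen after the data were examined.

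Over the whole list, summits lay near gene ends and inside genes more often than chance, and between genes less often. Summits within 500 bp of a gene end made up 23.6% of regions, against 18.1% ± 0.214 (SD over 1000 placements; permutation p = 0.000999, the smallest they can give). Gene interiors held 63.4% against 56.1%, and intergenic sequence 12.98% against 25.8%. Placements were not limited to sequence where reads can be mapped, so how far that makes these differences cannot be told. The excess at gene ends depended on distance. Within 200 bp the share was 8.84% against 8.73% (permutation p = 0.4835). The 2658 strong regions, the 10% with the highest fold (at least 2.999), behaved differently: 23.6% lay within 200 bp of a gene end against 8.69%, and 37.0% within 500 bp against 17.9% (permutation p = 0.000999 for each). Inside genes strong regions were below chance, with 48.8% against 56.3% (permutation p = 0.000999), where weaker regions were above it, with 65.1% against 56.1%. Weaker regions had 7.20% of summits within 200 bp against 8.73%, below chance (permutation p = 0.000999), but 22.1% within 500 bp against 18.1% and 40.8% within 1000 bp against 28.7%, above it.

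**Figure D1:**
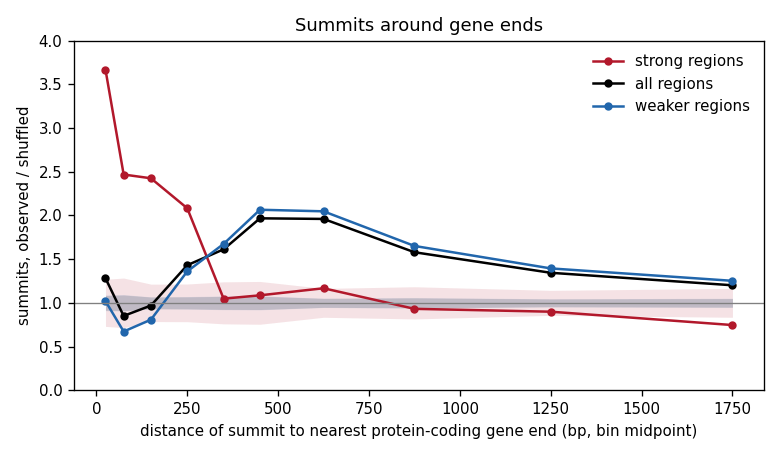
Summits observed over shuffled (y) by distance to the nearest protein-coding gene end in bp (x), for all, strong and weaker regions; shading is 2 SD of 1000 placements around 1. Strong regions reach 3.67 within 50 bp, while weaker regions are at 0.672 from 50 to 100 bp and at 2.07 in the bin that ends at 500 bp.

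Gene-end regions scored higher than distal regions. The median score was 87 at 6265 gene-end regions and 70 at 20306 distal regions, a difference of 17 (permutation test, two-sided, p = 1e-05, the smallest it can give). Within the strong regions the medians were 640.5 and 628.5 (permutation p = 0.6343).

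X, 4 and Y carried fewer regions than chance. X had 3623 regions, 0.796 of the number placed at random, chromosome 4 had 98 (0.398) and Y had 18 (0.0254), each with permutation p = 0.000999. Mappability and the copy number of each chromosome in these cells were not taken into account, so a shortfall need not mean less accessible chromatin. The Y regions had a median pileup of 365 reads and a median background of 84.7, against 105 and 47.6 on X. Arm 2R had 1.14 times the random number, 2L 1.11, 3L 1.07 and 3R 1.03, ratios that the shortfall on X and Y raises because the total is fixed. In the 50% with the higher score 3R was below chance, at 0.948 (permutation p = 0.001998), as it was among strong regions (0.893). Among strong regions X was at 1.07 (489 regions, permutation p = 0.08192) and chromosome 4 at 0.857 (21 regions, p = 0.5205), while Y stayed low at 0.184 (13 regions, p = 0.000999).

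Local background was raised over 3 long stretches, found after the data were examined as the longest runs of 100-kb bins at 1.5 times the lowest background or more. The longest, 2R 22.8 to 24.3 Mb, had a median background of 90.0 reads at its 553 regions against 48.1 on the rest of the arm, and a median pileup of 169 reads against 98. On 3L from 3 to 3.4 Mb the background was 76.4 reads against 47.3, and on X from 1.3 to 1.7 Mb it was 68.8 against 46.8. The median fold on the 2R stretch was 1.76.

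**Figure D2:**
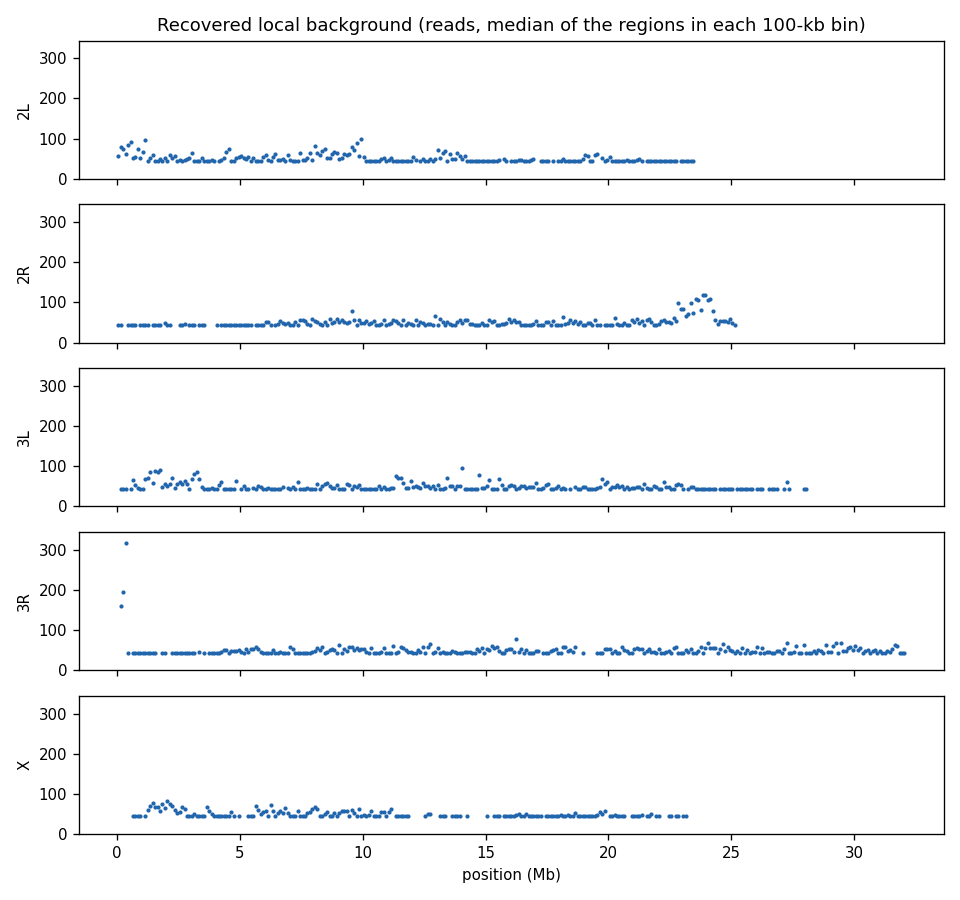
Recovered local background in reads (y), as the median of the regions in each 100-kb bin with at least 5 regions, by position in Mb (x) along 2L, 2R, 3L, 3R and X. The 2R stretch has a median of 90.0 reads, and the highest bins lie near the start of 3R.

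Developmental genes known from other work as Polycomb targets stood out among the gene lists. A region lay at an end of 51 of 55 Polycomb target genes (92.7%, against 68.5% of other protein-coding genes; Fisher's exact test, adjusted p = 0.0002452). Ribosomal protein genes (81 of 92, Fisher adjusted p = 0.0002452) and proteasome genes (42 of 48, adjusted p = 0.02301) were also higher. Neuron genes were lower, with 4 of 20 (Fisher adjusted p = 0.0002452), as were testis genes (7 of 18, adjusted p = 0.043) and chemoreceptor genes (101 of 179, adjusted p = 0.004031). Polycomb targets and ribosomal protein genes also passed with windows of 200 and 1000 bp, in the 50% with the higher score and with the summit inside the window. Proteasome and testis genes passed under none of these 4 settings, neuron genes not at 200 bp (Fisher adjusted p = 0.1161) and chemoreceptor genes not by summit (0.09092). The neuron genes ChAT, Gad1 and Rab3, which serve transmitter synthesis and release, had no region at an end. Neither did the chemoreceptor genes Gr10b, Gr22a and Gr22b or the testis genes Mst84Db, Mst84Dc and Mst84Dd. Gr22a and Gr22b are neighbours, as are these Mst84D genes, and the testis genes Mst98Ca and Mst98Cb share a region. Fisher's exact test counts such genes as independent, so its p-values can be too small for families that lie in clusters. The main test was also not matched on gene spacing. Of the 2260 isolated genes, whose ends lie over 1000 bp from other genes' ends, 52.4% had a region at an end. Among all protein-coding genes it was 68.6%. With isolated genes the lists called were the Polycomb targets (Fisher adjusted p = 1.703e-07) and the wing and haltere disc genes (adjusted p = 0.01546). Neuron genes kept a log2 odds ratio of -2.95 there but did not pass (Fisher adjusted p = 0.3582).

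The other 20 lists did not pass at 500 bp, though wing and haltere, leg and antenna, gut protease, Notch and cuticle protein genes passed under some other settings. The 20 were Hox genes (5 of 8), Polycomb proteins (16 of 19), factors that bind Polycomb response elements (6 of 9) and Trithorax group (10 of 13). Disc lists were wing and haltere (27 of 32), leg and antenna (17 of 20) and eye (13 of 17). Signalling lists were Notch (13 of 16), ecdysone (11 of 16) and Hippo (13 of 15). Insulator proteins had 13 of 14, dosage compensation 6 of 8 and heat shock 12 of 17. Tissue lists were hemocyte (13 of 17), glia (7 of 11), muscle (10 of 21), germline (9 of 14), fat body and eggshell (13 of 16), gut proteases (23 of 27) and cuticle proteins (62 of 97).

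Wing and haltere disc genes, leg and antenna disc genes and Polycomb targets stood out further with strong regions. A strong region lay at an end of 28 of 55 Polycomb targets (50.9%), 20 of 32 wing and haltere disc genes (62.5%) and 12 of 20 leg and antenna disc genes (60%), against 11.1% to 11.2% of other genes. The adjusted p-values, by Fisher's exact test, were 1.08e-11, 7.531e-11 and 1.738e-06. Eye disc genes, with 4 of 17, did not pass (Fisher adjusted p = 0.2159). The target list shares 17 genes with the wing list and 8 with the leg list. The 30 targets outside the 3 disc lists still had 12 with a strong region (40%, Fisher's exact p = 4.98e-05, not adjusted). The 36 disc genes outside the target list had 15 (41.7%, Fisher's exact p = 3.126e-06, not adjusted). The excess was therefore not particular to either kind of list. Among the disc genes of the target list, dac, a leg and eye patterning factor, had a fold of 10.7 at its upper end (2L 16485661 to 16486551, interval 9.82 to 11.7). The trunk patterning gene tsh had 10.3 (2L 21828054 to 21829217) and the Wnt ligand gene wg 8.64 (2L 7306863 to 7307633, interval 7.81 to 9.54). Folds for caup and Dll were 6.73 and 4.19, and those for Dr and wor, outside the disc lists, both 6.58. By contrast hth, with 28 distal regions, had none at either end, nor had eya or sna.

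Heat shock genes were also higher among strong regions, with 6 of 17 (Fisher adjusted p = 0.0363), among them Hsp83 (fold 3.40), Hsp70Ab (3.92) and DnaJ-1 (3.84). The other members, Hsp23 (3.15), Hsp67Ba (3.09) and Hsp27 (3.01), are neighbours on 3L with intervals that include the limit of 2.999. Chemoreceptor genes (2 of 179, Fisher adjusted p = 1.738e-06) and cuticle protein genes (2 of 97, adjusted p = 0.009174) were lower. Ribosomal protein (14 of 92, Fisher adjusted p = 0.3974), proteasome (6 of 48, 0.9663), neuron (1 of 20, 0.9423) and testis genes (3 of 18, 0.6841) did not differ past the threshold. Polycomb proteins had 5 of 19 (Fisher adjusted p = 0.158), and these 5 had high folds: jing 10.4, ph-p 8.77, ph-d 7.88, Su(z)2 7.09 and Psc 6.79. Factors that bind Polycomb response elements had 3 of 9 (Fisher adjusted p = 0.1856), which were Dsp1 (8.67), cg (5.90) and z (3.03).

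**Figure D3:**
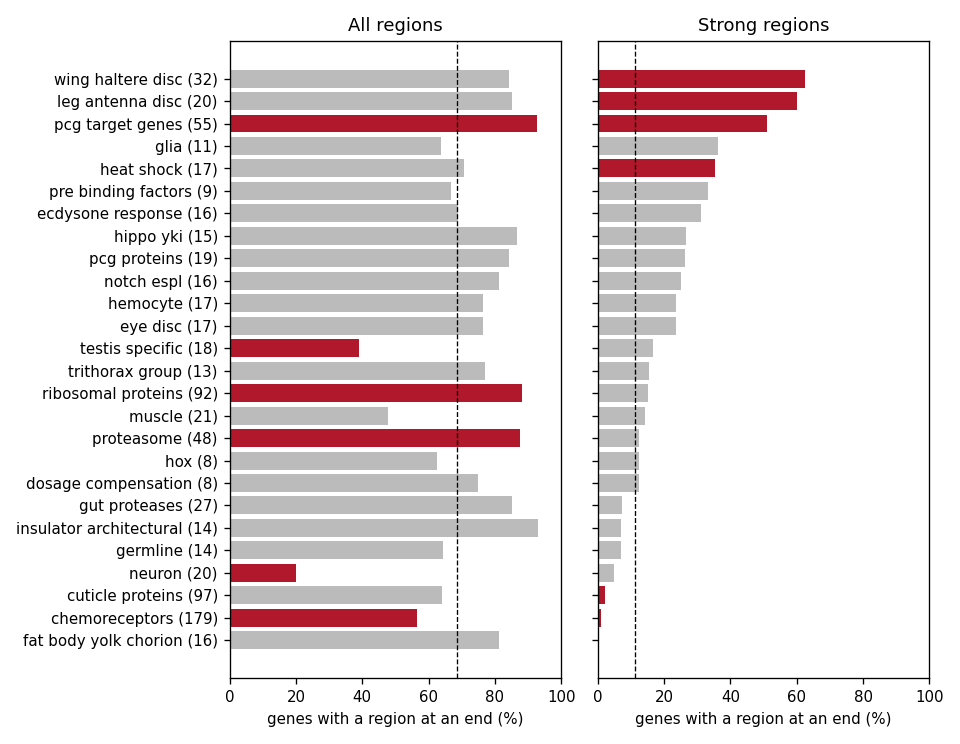
Percent of the genes of each list (number in brackets) with a region at either end, for all regions and for strong regions; red bars pass an adjusted p of 0.05 (Fisher's exact test over 26 lists) and the dashed line is the share among other genes. Polycomb targets reach 92.7% with all regions and 50.9% with strong regions.

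The Hox genes, which set segment identity, had folds of 1.81 to 3.70 at the ends that carried a region. A region lay at an end of lab (fold 3.70, interval 3.17 to 4.31), Scr (2.78), Dfd (2.16), Abd-B (1.85) and pb (1.81), and at no end of Antp, Ubx and abd-A. Only lab had a strong one. The strong regions of the bithorax complex lay away from these ends. The highest, 3R 16934142 to 16934974, was inside Abd-B (fold 8.32, interval 7.64 to 9.04). A region at 3R 16763808 to 16764342 inside lncRNA:bxd had 5.58 and another inside Ubx had 4.12 (3R 16702905 to 16703194). In the Antennapedia complex the highest fold, 7.23, was at 3R 7000627 to 7001193, past the upper end of Antp at 6999228. The bithorax complex held 33 regions and the Antennapedia complex 59, within 5000 bp of their outer genes. Random windows of those lengths on 3R held 15 to 101 and 17 to 107 (95% range).

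The neighbouring homeobox genes en and inv, which mark posterior compartments, had strong regions at their outer ends. The upper end of en lay in 2R 11526005 to 11528480, with a fold of 7.95 (interval 7.29 to 8.65) and a summit pileup of 537 reads. Within 500 bp of the lower end of inv was 2R 11474925 to 11476561, with 6.32 (5.79 to 6.88) and 531 reads. A strong region of fold 3.60 lay inside inv (2R 11491371 to 11493051). Summits over 500 bp from any gene end numbered 17 for inv, including that of the region at its lower end, and 4 for en. Strong regions at the locus numbered 6 within 5000 bp of the outer gene ends and 3 within 2000 bp, against a random 95% range of 0 to 6 for the longer window.

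**Figure D4:**
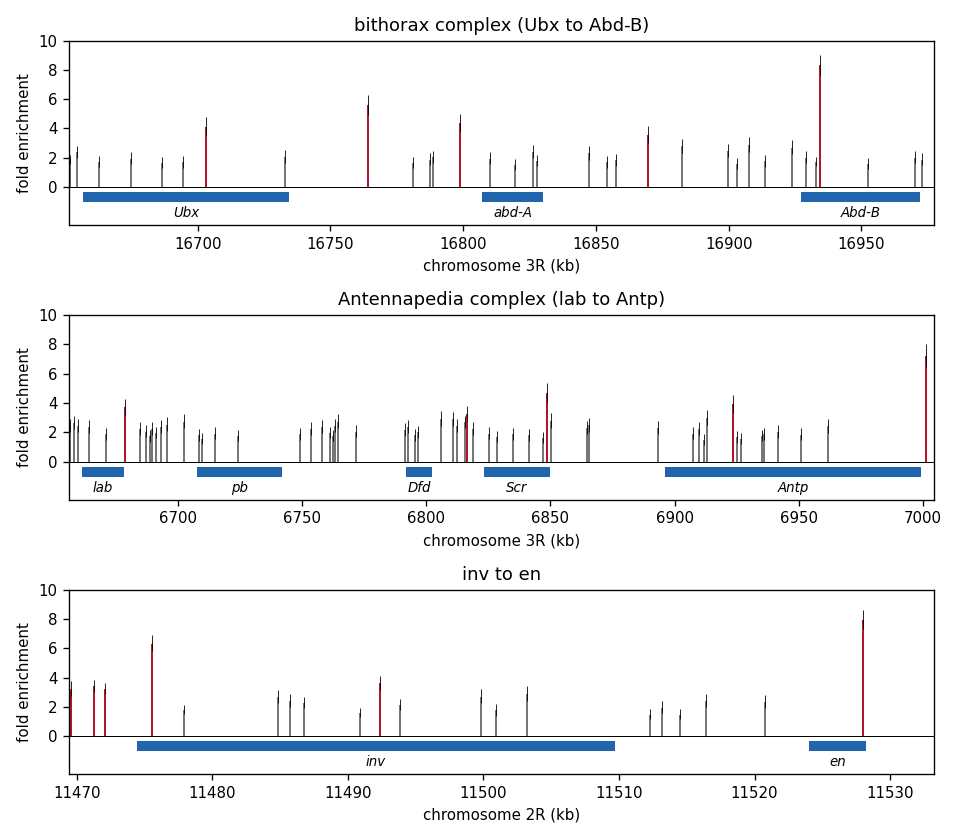
Fold enrichment (y, authors' value) at each summit along the bithorax complex, the Antennapedia complex and the inv to en locus (x, kb); red lines are strong regions, grey lines weaker ones, thin black bars 95% Poisson intervals, and blue boxes genes. The highest folds are 8.32, 7.23 and 7.95.

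Hemocyte genes had more distal regions than other genes of similar territory. Hemocyte genes averaged 3.41 distal regions against 1.82 in matched lists (95% range 1.06 to 2.65, permutation adjusted p = 0.0026), with srp, a blood cell GATA factor, at 8 and ush at 12. Polycomb proteins averaged 4.21 against 1.80 (permutation adjusted p = 0.04888), with jing at 34. Without jing they averaged 2.56 against 1.45 (permutation adjusted p = 0.009099). The full list, jing included, did not pass at 1000 bp (permutation adjusted p = 0.104) or with genes of any kind (0.1599). Gut proteases (0.0370 against 0.355, permutation adjusted p = 0.003466), chemoreceptors (0.978 against 1.40, adjusted p = 0.007799) and cuticle proteins (0.412 against 0.737, adjusted p = 0.0026) were lower. Gut proteases and cuticle proteins did not pass at 1000 bp or in the 50% with the higher score, nor chemoreceptors with genes of any kind. Polycomb targets averaged 5.51 against 4.39 (permutation adjusted p = 0.2604) and Hox genes 4.75 against 6.94 (adjusted p = 0.5678). The first test has little power for such long territories. Limiting matched genes to the longest territory of the list was a choice made after seeing the data. In simulations it also called 11 of 360 unrelated tests with nothing planted, 23 with 3 planted regions per gene and 18 with 8. Under this limit 5 more lists were higher. These were wing and haltere (permutation adjusted p = 0.001733), ecdysone (0.0026), Hippo (0.007149), Polycomb target (0.04448) and germline genes (0.04576). No list passed with strong regions in the first test. Myo81F had the most distal regions of any gene, 199 over a territory of 2543547 bp, followed by bru3 (86), Pzl (67), lovit (46), DIP-lambda (40) and br (39). Then came olf413 (37), nAChRalpha6 (36), jing (34), and Snap25 and bi with 32 each.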

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

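Strong regions, also when matched on territory, isolated genes and the territory limit were chosen after seeing the data. So were fold in place of score and lists without the member with the most distal regions. The other alternatives were chosen before. The list held 13286 regions in the 50% with the higher score and 2658 strong regions. The share at gene ends stayed above chance at 1000 bp, with any overlap, with protein-coding ends, in the higher-scoring 50% and in strong regions, but not at 200 bp (8.84%, permutation p = 0.4835); the cause was not tested. Arm 3R reversed in the higher-scoring 50% (0.948, permutation p = 0.001998) and in strong regions (0.893, p = 0.001998). The shortfall on X was not seen in strong regions, where its ratio did not pass (1.07, permutation p = 0.08192). In strong regions 2L (1.078, permutation p = 0.06593), 3L (1.03, p = 0.4266) and 4 (0.857, p = 0.5205) did not pass; the cause was not tested. At gene ends 6 lists passed at first, and their number, 5 to 7 under the alternatives chosen beforehand, hides changes of membership. At 200 bp neuron, proteasome and testis genes left and wing and haltere (Fisher adjusted p = 0.01046), leg and antenna (0.002288) and gut protease genes (0.0009951) entered. At 1000 bp proteasome and testis genes left and cuticle proteins entered (Fisher adjusted p = 0.03341). In the higher-scoring 50% proteasome and testis genes left and both disc lists entered. With the summit inside the window proteasome, testis and chemoreceptor genes left, and both disc lists, Notch and gut protease genes entered. With isolated genes, fewer in number, 2 lists passed. The log2 odds ratio of testis genes turned positive with strong regions (0.83, Fisher adjusted p = 0.6841) and that of chemoreceptor genes with isolated genes (0.19, adjusted p = 1). Distal regions gave 5 lists, the same 5 when also matched on a region at an end or without the top member. Hemocyte genes passed under each alternative but strong regions. In the higher-scoring 50% 3 passed, without gut protease (permutation adjusted p = 0.09953) and cuticle genes (0.09879). At 1000 bp 2 passed, without Polycomb proteins (permutation adjusted p = 0.104), gut protease (0.4765) and cuticle genes (0.104). With genes of any kind 3 passed, without Polycomb proteins (permutation adjusted p = 0.1599) and chemoreceptors (0.08059). With strong regions 0 passed, though 6 had an unadjusted p under 0.05, and with the territory limit 10 passed. In simulated data the territory limit called 11 of 360 unrelated tests with nothing planted, 23 with 3 planted regions per gene and 18 with 8. The score difference in strong regions was 12 (permutation p = 0.6343). The motif alternatives and the 5′-most start site were not run. No paired analysis was possible because there is 1 group, and no replicate could be left out because the list names none. The lowest recovered summit pileup was 62 reads, and how detection depends on depth was not tested.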

Other observations

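The tests of both patterns weighed here were chosen after the results were seen, as were the genes named in the next paragraph.

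Strong regions at ends also marked single members of lists that did not pass as a whole. The muscle fusion gene sns had a fold of 9.72 (2R 8798078 to 8799149) and the glial receptor gene moody 8.54 (X 2049936 to 2050897). In the leg and antenna list and the wing and haltere list, which passed with strong regions, disco had 9.57 (X 16216573 to 16217916) and the Dpp pathway repressor gene brk 8.22. Genes with many strong distal regions included Myo81F (40), DIP1 (9), psq, fru and the ecdysone-induced gene Eip74EF (8 each). Ecdysone response genes averaged 2.31 strong distal regions against 0.549 in matched lists (permutation p = 0.0234, adjusted p = 0.1341), so the list did not pass.

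Weaker regions were below chance within 200 bp of gene ends but above it within 500 bp (22.1% against 18.1%), and inside protein-coding genes under 2000 bp at 2.31 times chance (12.96% against 5.60% ± 0.136). Inside genes of 10000 bp or more weaker regions were at 0.899 of chance (42.3% against 47.0% ± 0.281), so no excess was seen there. That cannot decide on enhancers in long introns, since exons and introns were not separated and placements included sequence where reads cannot be mapped. Uneven background coverage that follows gene bodies whether or not a gene is used may contribute. Chemoreceptor, cuticle, gut protease and testis genes were pooled, without a test of whether each family is unused in these cells. Inside them weaker summits were at 1.84 times chance (241 against 131 ± 10.6), while strong summits were not above it (7 against 13.9). Protein-coding genes under 2000 bp in general showed the same contrast, at 2.31 times chance for weaker and 0.639 for strong summits. No expression was measured here, so these families do not single out background coverage. Whether base composition underlies this was not tested, since no sequence was used, and beyond the check of long genes no biological explanation was tested.

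A stretch of 2R from 22.8 to 24.3 Mb was picked for its raised background, with a median of 90.0 reads against 48.1 elsewhere on the arm. Extra copies of the segment stay open: the median fold differed from the rest of the arm by -0.137 (95% bootstrap range -0.170 to -0.0864), but a higher background lets lower folds pass the q threshold under any explanation. More genes or regions per length stay open too. The median over the bins of the stretch was 97.6 reads. In 48 bins elsewhere with at least its median numbers of regions and genes, the median was 58.1 reads. The stretch lay at the 97.9 percentile of those bins. But 1 of them reached 98.2, and the stretch was picked on this value. No biological explanation was tested.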
